A study of Homo sapiens with 12 samples.

How the data were processed

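Gene expression was measured by RNA-seq of total RNA from parental and cisplatin-resistant H226, H460 and PC9 cells, 12 libraries in 6 groups of 2. Per the labels' protocols, cells grew in RPMI medium, RNA was taken with TRIzol before the cultures were confluent, and libraries were run on a NovaSeq instrument. The values are counts of reads per gene as deposited, in 1 table per line. The submitters' processing notes name FastQC, MultiQC, Trim Galore, HISAT2, featureCounts and DESeq2 and the build GRCh38, without versions. They do not state the library kit, whether strand was used in counting, or how reads that match several genes were treated. Values of antisense genes, of overlapping genes and of genes with near-identical copies (HLA, GSTM, histone, ribosomal protein and mitochondrial genes) are therefore uncertain.

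All columns held whole numbers, with totals between 32282639 and 40361545 counts per library. Each table listed 63241 genes, of which 20601 had no symbol, and no column of another sample. In each table the record of 1 gene had been split over several lines and was restored. Identifiers, symbols, biotypes and GRCh38 coordinates were taken from the tables, and synonyms from a RefSeq gene table. Before the data were examined, the comparisons, tests, gene lists, rule for named genes and alternatives were fixed from the labels, except for those alternatives and tests that the closing section names as added later.

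edgeR 4.0.16 in R 4.3.3 was used with TMM scaling and the filterByExpr rule on the 6 groups, which left 28129 genes. A quasi-likelihood model with a mean per group (robust fit, trended dispersion, 6 residual degrees of freedom) was fitted to the 12 libraries together, because 2 libraries against 2 leave 2 residual degrees of freedom. Resistant was compared with parental within each line, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Shared genes are those called in the same direction in all 3 lines, beside the number expected of independent calls. A common change was tested in an additive model of line and status, and a difference between lines by a quasi-likelihood F-test that the 3 changes are equal, with the pairwise differences. CPM are scaled by TMM, and SD are between the 2 libraries of a group. The SE of a log2 fold change is its size divided by the square root of the F statistic of its test.

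Lists of genes were written from textbook knowledge and tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over lists within a contrast. They cover platinum and copper transport, metallothioneins, NRF2 and glutathione, nucleotide excision repair, homologous recombination and Fanconi anaemia, translesion synthesis and mismatch repair, p53 targets, anti-apoptotic and pro-apoptotic genes, epithelial and mesenchymal markers, YAP/TEAD, TGF-beta and MAPK targets, S phase and mitosis. The others cover interferon-stimulated genes, HLA class I and class II, NF-kB and cytokines, hypoxia and glycolysis, cholesterol synthesis, the integrated stress response, squamous, alveolar, neuroendocrine and stemness markers, cancer-testis antigens, receptor tyrosine kinases, lncRNAs of drug response, markers of immune, endothelial, fibroblast or mesothelial and red cells, histones, mitochondrial messenger RNAs, ribosomal proteins, and heat shock or immediate early genes. None of the calls made with the preset correlation held when the correlation was estimated from the data. For each list the genes called over all tested genes and those adjusted over the list alone were counted.

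Named genes followed a rule. For each line it took the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes of at least 10 CPM in the higher group whose groups did not overlap, and the 3 lncRNAs each way of at least 1 CPM. For shared genes it took 10 protein-coding genes and up to 6 lncRNAs each way by mean change, and for each list described in a line up to 2 called members each way with the smallest adjusted p. The genes it always took included NR2F1-AS1, NR2F1, NKX2-1-AS1, NKX2-1, ERCC1, SLC31A1, ATP7A, ATP7B, ABCC2, EGFR, KEAP1 and NFE2L2. Some genes that these rules took are not reported here. All 80 called genes named for H226, 92 for H460 and 78 for PC9 had both resistant libraries on 1 side of both parental libraries. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library. With 1 to 3 counts, a ratio with its exact 95% binomial interval is given. Bounds and intervals cover counting error only.

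The procedure was tested on simulated counts over 28129 genes, drawn from the means of the parental libraries and the dispersions and library sizes of these data. Changed genes were few, 335, 335 and 330 per line at 1.5-fold, 2-fold and 4-fold over 5 simulations. They were chosen by a minimum mean count over the 12 libraries, so some could be scarce in the line where they were changed. Recovery of scarce genes was not tested on its own. The real data held far more called genes, so the simulated share of false calls need not hold for them. For H226, H460 and PC9 it recovered 49.9%, 49.3% and 51.3% of genes changed by 1.5-fold, 71.6%, 78.2% and 74.6% of those changed by 2-fold and 91.8%, 90% and 90.3% of those changed by 4-fold. False calls made up 14.5%, 7.5% and 8.9% of calls in H226, H460 and PC9, above the 5% that the threshold aims at, so calls near the threshold are less certain than their adjusted p. In a list simulation for H460, 4 of 4 raised lists and 0 of 4 other lists were called. Its genes were drawn independently, so it could not test list calls where members of a list are correlated. In shuffled fold changes of PC9 3 of 3 shifted chromosome windows were called with 2 others.

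Alternatives were DESeq2 size factors in edgeR, no count filter, at least 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, a log2 fold change of at least 1, DESeq2 1.42.0 on all libraries or each line alone, edgeR on each line alone, the mean of the line contrasts, each line left out for the common change, camera with an estimated correlation, with voom weights or with the block, and 5 Mb windows or chromosome arms for positions. The text leaves out genes without a symbol, and no sequence reads were available.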

Results

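Total RNA was sequenced from 3 human non-small cell lung cancer lines, H226, H460 and PC9, and from the cisplatin-resistant derivative of each, with 2 libraries in each of the 6 groups. H226 is usually described as a squamous line, H460 as a large cell line and PC9 as an adenocarcinoma line with an activating EGFR mutation. The resistant cells were maintained in 1 µM cisplatin for H226, 0.83 µM for H460 and 6.6 µM for PC9, and had been out of the drug for 1 week when they were used. Each library held between 32282639 and 40361545 assigned counts, and 28129 of the 63241 annotated genes passed the count filter. Changes are log2 fold changes of resistant over parental cells ± SE, from 2 libraries per group, unless given as a fold. The SE was derived from the F statistic, and can be too small for large changes where 1 group had few counts. Nothing in the labels says that the libraries of a group came from separate cultures, so adjusted p-values measure the spread between these libraries, which can be technical.

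Whether each resistant line still resembles its parental line was examined first, through the correlation of log2 CPM (counts scaled to library size) between libraries across 20545 genes. H460 resistant libraries correlated with their own parental libraries at a mean r of 0.923 and PC9 resistant libraries at 0.958, against at most 0.777 and 0.77 with any group of another line. The libraries labelled H226 resistant correlated at 0.744 with H226 parental libraries and at up to 0.766 with a group of another line. Libraries of 1 group correlated at 0.979 to 0.984. All 4 H226 libraries differed from the other 8 in RNA composition, with at most 0.007% ribosomal RNA against at least 0.598% and at least 0.5% histone RNA against at most 0.0326%, so correlations between H226 and the other lines span a difference that can stem from how RNA was selected. NF2 and BAP1, tumour suppressor genes often lost in mesothelial cancers, had 0.06 ± 0.0848 and 0.12 ± 0.17 CPM in H226 parental libraries, against 161 ± 10.7 and 37.9 ± 0.164 CPM in the libraries labelled H226 resistant (mean ± SD). CDKN2A, a cell cycle inhibitor gene on chromosome 9, went the other way, from 11.9 ± 0.142 to 0.0632 ± 0.0894 CPM. The keratin gene KRT5 went from 47.6 ± 7.98 CPM to 0 counts. NF2, BAP1 and CDKN2A were singled out as markers after their values were seen. For these reasons genes of H226 alone are described after those of H460 and PC9, and a rise or fall in H226 is throughout a difference between libraries by their labels.

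**Figure D1:**
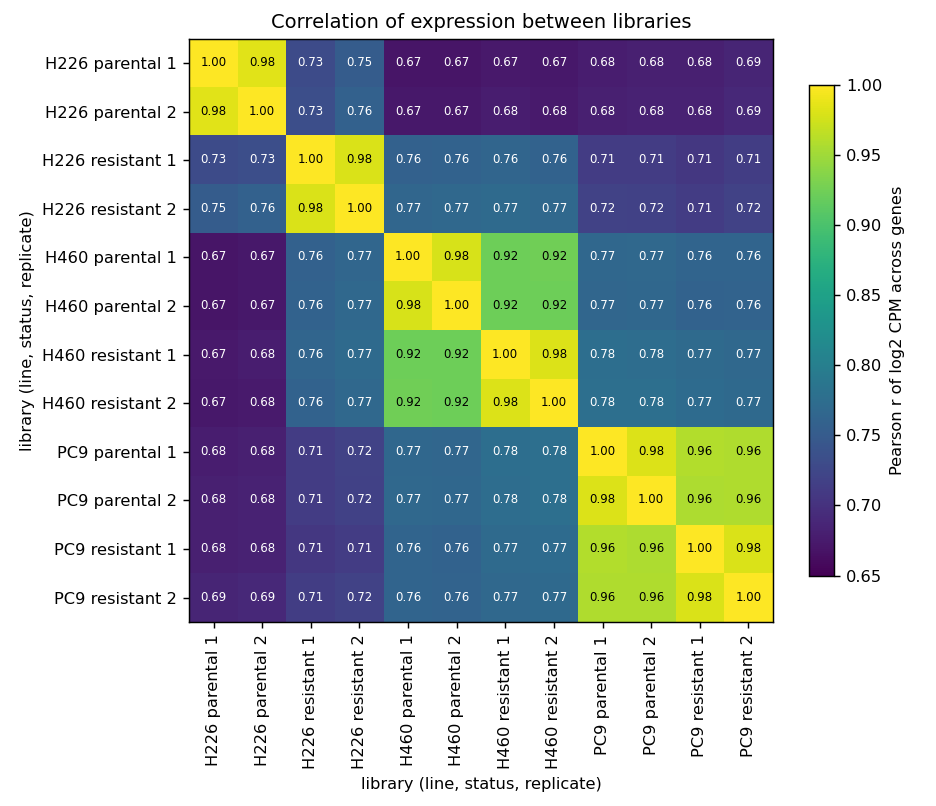
Pearson r of log2 CPM across 20545 genes between all 12 libraries, each axis listing the libraries by line, status and replicate. Libraries labelled H226 resistant have a mean r of 0.744 with H226 parental libraries, while the resistant libraries of H460 and PC9 have 0.923 and 0.958 with theirs.

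The title of the series names a long non-coding RNA, NAS1, whose loss was to be related to resistance. NAS1 is a synonym of NR2F1-AS1 (ENSG00000237187, chromosome 5, 93360779 to 93585649, minus strand, GRCh38) in the gene reference used here, and the labels do not say which gene the title means. NR2F1-AS1 fell in all 3 lines, by 2.51 ± 0.20 in H226, 3.28 ± 0.23 in H460 and 2.26 ± 0.26 in PC9 (adjusted p = 9.4e-11, 2.6e-11 and 3.97e-07). Its mean ± SD was 38.3 ± 3.34 CPM in parental and 6.75 ± 0.379 CPM in resistant libraries of H226. In H460 the values were 20.1 ± 2.01 CPM in parental and 2.06 ± 0.42 CPM in resistant libraries, and in PC9 they were 5.58 ± 0.281 CPM in parental and 1.16 ± 0.64 CPM in resistant libraries. NR2F1, the orphan nuclear receptor gene that NR2F1-AS1 overlaps on the opposite strand, changed by −4.44 ± 0.17, −1.60 ± 0.16 and −2.97 ± 0.34 in the same lines, with a largest adjusted p of 4.99e-07. Whether the counting used strand is not stated, so reads of NR2F1 and NR2F1-AS1 cannot be fully told apart. The size of the NR2F1-AS1 change differed between lines (adjusted p = 0.0323), and both resistant libraries lay below both parental libraries in each line. SLC13A1, which shares the synonym NAS1, had 0 counts in every library. NKX2-1 and NKX2-1-AS1, named in advance as another antisense pair of the lung, were below the count filter.

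**Figure D2:**
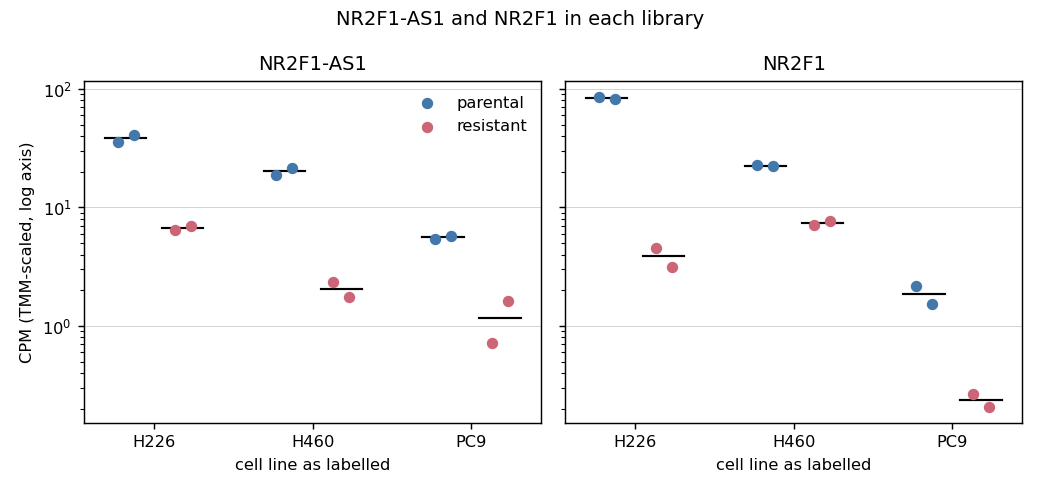
CPM of NR2F1-AS1 and NR2F1 in each library on a log axis, by line and status, with points for libraries and bars for the mean of 2. NR2F1-AS1 means fall from 38.3 to 6.75 CPM in H226, from 20.1 to 2.06 in H460 and from 5.58 to 1.16 in PC9.

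The comparison of H460 resistant with H460 parental cells asks which genes moved with resistance in that line. TGFA, which encodes a ligand of EGFR, rose by 11.57 ± 0.24, from 0.443 ± 0.0495 to 1360 ± 75.6 CPM. TNC, which encodes the matrix protein tenascin-C, had 0 counts in both parental libraries and was at least 964-fold higher in resistant ones. MAGEB17, a cancer-testis antigen gene on chromosome X, was likewise at least 1000-fold higher, together with MAGEB17-AS1 (at least 768-fold) and GRPR (at least 493-fold). MAGEB17-AS1 overlaps both MAGEB17 and GRPR, and can share reads with each when strand is not used. SPINK6, F13A1, OLFML3 and the dopamine receptor gene DRD2 were at least 238-fold, 152-fold, 132-fold and 104-fold higher. SLFN11, whose low expression has been tied to resistance to DNA-damaging drugs, went from 56.9 CPM to 0 counts and was at least 595-fold lower. SEMA3E was at least 893-fold lower, LGSN 137-fold, P2RX5 122-fold, GABRG1 121-fold and ZNF568 111-fold, each a lower bound against 0 counts. The ephrin receptor gene EPHA3 fell by 9.19 ± 0.40 and SERPINB11 fell by 11.21 ± 0.30, though DESeq2 on the 12 libraries did not call SERPINB11 at a log2 fold change of −11.33. Among non-coding genes, ADAMTS16-DT and LINC00973 were at least 108-fold and 71.2-fold higher, and LRFN5-DT and DSCAM-AS1 at least 23.1-fold and 17.6-fold lower. MEF2C-AS2 was lower by 178-fold (95% counting interval 48.9 to 1480) and was not called by DESeq2 on the 12 libraries. The largest adjusted p among these genes was 0.000147. In all, 5191 genes were called higher (4328 protein-coding, 704 lncRNA) and 4681 lower (3857 and 567) by edgeR's quasi-likelihood test.

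Interferon, HLA class I and NF-kB lists were called upward in H460 resistant cells with the preset correlation, through most but not all members. OASL, an antiviral gene induced by interferon, rose by 7.92 ± 0.25 and the ubiquitin-like ligase gene HERC5 by 5.31 ± 0.17, whereas OAS1 fell by 2.94 ± 0.13. The interferon-stimulated genes had 24 of 38 members higher and 1 lower, 25 and 1 adjusted over the list alone (camera adjusted p = 6.08e-08, adjusted p = 0.249 with an estimated correlation). HLA-B and HLA-C, which present peptides to T cells and share reads with other HLA genes, rose by 2.43 ± 0.15 and 1.44 ± 0.11. HLA class I presentation genes had 14 of 18 members higher and 1 lower, 15 and 1 adjusted over the list alone (camera adjusted p = 0.000141, adjusted p = 0.284 with an estimated correlation). BIRC3, an inhibitor of apoptosis induced by NF-kB, rose by 2.12 ± 0.12 and the neutrophil chemokine gene CXCL1 by 1.75 ± 0.12. NF-kB and cytokine genes had 17 of 26 members higher and 1 lower, 17 and 1 adjusted over the list alone (camera adjusted p = 1.88e-06, adjusted p = 0.145 with an estimated correlation).

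Growth factor and matrix signalling genes moved as well. PMEPA1, a feedback target of TGF-beta, rose by 5.27 ± 0.12 and the receptor gene TGFBR1 by 3.06 ± 0.10. TGF-beta targets had 14 of 20 members higher and 2 lower, 14 and 3 adjusted over the list alone (camera adjusted p = 1.5e-05, adjusted p = 0.145 with an estimated correlation). Beside TGFA, the receptor tyrosine kinase gene EPHB2 rose by 6.99 ± 0.31 and the ligand gene EGF fell by 1.62 ± 0.19. Receptor tyrosine kinases and ligands had 19 of 29 members higher and 2 lower, 19 and 2 adjusted over the list alone (camera adjusted p = 3.24e-05, adjusted p = 0.145 with an estimated correlation). Feedback genes of the MAPK pathway split, with IER3 up by 3.02 ± 0.12 and SPRY4 by 2.48 ± 0.11, while MYC fell by 2.67 ± 0.11 and the ERK phosphatase gene DUSP6 by 1.505 ± 0.134. The MAPK list had 12 of 24 members higher and 3 lower, 14 and 3 adjusted over the list alone (camera adjusted p = 0.00152, adjusted p = 0.326 with an estimated correlation). NT5E and CRIM1 rose by 2.48 ± 0.10 and 1.93 ± 0.10 and AJUBA fell by 1.10 ± 0.11 among YAP/TEAD targets, which had 12 of 23 members higher and 6 lower, 14 and 6 adjusted over the list alone (camera adjusted p = 0.0314, adjusted p = 0.479 with an estimated correlation).

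Stress, metabolic and cell cycle lists moved in both directions in H460. AKR1B10, an aldo-keto reductase gene activated by the oxidative stress factor NRF2, fell by 5.24 ± 0.14 and the thioredoxin reductase gene TXNRD1 by 1.04 ± 0.08. NRF2 targets and glutathione genes had 0 of 33 members higher and 27 lower, 1 and 27 adjusted over the list alone (camera adjusted p = 6.08e-08, adjusted p = 0.281 with an estimated correlation). TRIB3 and the serine synthesis gene PSAT1, both induced by ATF4, fell by 3.00 ± 0.12 and 2.84 ± 0.11, while the chaperone gene PDIA4 rose by 1.11 ± 0.10. Integrated stress and unfolded protein response genes had 8 of 32 members higher and 20 lower, 9 and 20 adjusted over the list alone (camera adjusted p = 0.000124, adjusted p = 0.284 with an estimated correlation). ENO2 and PKM, which encode glycolytic enzymes, rose by 3.52 ± 0.12 and 1.15 ± 0.09, and PDK1 fell by 1.89 ± 0.10. Hypoxia and glycolysis genes had 21 of 32 members higher and 3 lower, 22 and 3 adjusted over the list alone (camera adjusted p = 0.000394, adjusted p = 0.284 with an estimated correlation). UHRF1 and TK1, which are expressed in S phase, rose by 1.63 ± 0.10 and 1.34 ± 0.10, and the S phase list had 25 of 35 members higher and 1 lower, 26 and 1 adjusted over the list alone (camera adjusted p = 6.38e-07, adjusted p = 0.145 with an estimated correlation). SLC31A1, the copper importer through which platinum can enter cells, fell by 1.32 ± 0.08 and the efflux pump gene ABCG2 by 2.26 ± 0.12, while the copper exporter gene ATP7A and the volume-regulated channel gene LRRC8C rose by 0.91 ± 0.12 and 2.23 ± 0.18.

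Lists of ribosomal protein, mitochondrial and handling genes, often read as measures of RNA composition, were called in H460 as well, and no test here shows why. Ribosomal RNA took 1.7% and 1.67% of counts in H460 parental and 0.598% and 0.696% in H460 resistant libraries. RPLP0, a ribosomal protein gene, fell by 1.04 ± 0.09, and ribosomal protein genes had 0 of 58 members higher and 46 lower, 0 and 47 adjusted over the list alone (camera adjusted p = 7.03e-10, adjusted p = 0.326 with an estimated correlation). Their share of all counts was 7.96% and 6.68% in the parental libraries and 5.49% and 5.4% in the resistant ones, and pseudogene copies can take some of their reads. MT-ND3 fell by 0.72 ± 0.10, and mitochondrial messenger RNAs had 0 of 13 members higher and 9 lower, 0 and 9 adjusted over the list alone (camera adjusted p = 0.00714, adjusted p = 0.444 with an estimated correlation). Without H460 parental replicate 2 the mitochondrial list was not called (camera adjusted p = 0.076), and mitochondrial genes took 5.46% and 5.95% of counts in parental against 3.86% and 3.79% in resistant libraries. The chaperone gene HSPA8 and the immediate early gene JUN rose by 1.79 ± 0.09 and 2.60 ± 0.15, in a handling list that had 11 of 14 members higher and 1 lower, 12 and 1 adjusted over the list alone (camera adjusted p = 1.65e-06, adjusted p = 0.0557 with an estimated correlation). SNHG1, a host gene of small nucleolar RNAs, fell by 1.95 ± 0.11 and LINC00511 rose by 3.78 ± 0.21 in a separate list of lncRNAs studied in drug response, which had 5 of 58 members higher and 24 lower, 5 and 25 adjusted over the list alone (camera adjusted p = 0.00449, adjusted p = 0.249 with an estimated correlation).

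In PC9, the same question was put to the line kept at the highest cisplatin concentration. HLA-B rose by 4.35 ± 0.19, from 2.13 to 43.6 CPM. HLA class I presentation genes had 9 of 18 members higher and 0 lower, 9 and 0 adjusted over the list alone (camera adjusted p = 0.000193, adjusted p = 0.547 with an estimated correlation). The secreted BMP antagonist gene GREM1 rose by 3.82 ± 0.24, the neuropeptide gene NMU by 5.56 ± 0.36, REEP1 by 3.98 ± 0.32, the lysosomal GTPase gene RRAGD by 3.79 ± 0.25 and CHST10 by 3.43 ± 0.20. MUCL3, beside the HLA genes on chromosome 6, was at least 125-fold higher, and HCG21, which overlaps it, at least 37.3-fold, although DESeq2 on the 12 libraries did not call HCG21. HMGA2, a chromatin protein gene repressed by let-7, was lower by 983-fold (95% counting interval 336 to 4770). GSTM1, a glutathione transferase gene whose reads can be shared with its GSTM paralogs, was at least 183-fold lower. CDYL2 was at least 358-fold lower, the prostaglandin dehydrogenase gene HPGD 236-fold, TSPYL5 176-fold, SLITRK6 145-fold, ARHGAP28 133-fold and KLF12 130-fold, each against 0 counts in resistant libraries. LINC01060, LINC02315 and LINC01322 were at least 84.4-fold, 12.7-fold and 25.5-fold lower, and DESeq2 on the 12 libraries did not call LINC01322. BVES-AS1 was higher by 104-fold (95% counting interval 18.4 to 4160) and LINC00494 by 36.6-fold (95% counting interval 9.79 to 308). LINC00494 lost its call without parental replicate 2 (log2 fold change 4.19) or resistant replicate 1 (4.47). The largest adjusted p among these genes was 0.00568. In all, 2756 genes were called higher (2487 protein-coding, 221 lncRNA) and 2792 lower (2301 and 394), and the higher count was 1816 without parental replicate 2.

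Homologous recombination and cell cycle lists moved modestly in PC9. BRCA1, the homologous recombination gene, rose by 1.04 ± 0.09 and the end resection gene RBBP8 by 0.94 ± 0.09, while FANCF fell by 0.88 ± 0.15. Homologous recombination and Fanconi genes had 17 of 36 members higher and 3 lower, 18 and 3 adjusted over the list alone (camera adjusted p = 0.00021, adjusted p = 0.547 with an estimated correlation). CDC45 and MCM3, parts of the replicative helicase, rose by 0.87 ± 0.11 and 0.75 ± 0.09, and GINS1 fell by 0.77 ± 0.09. S phase genes had 13 of 35 members higher and 5 lower, 16 and 5 adjusted over the list alone (camera adjusted p = 0.00996, adjusted p = 0.547 with an estimated correlation), and were not called without parental replicate 1 (camera adjusted p = 0.107). The spindle gene DLGAP5 and the anaphase activator gene CDC20 fell by 1.09 ± 0.10 and 0.69 ± 0.10, and the kinetochore gene NDC80 rose by 0.54 ± 0.10. Mitosis genes had 3 of 36 members higher and 15 lower, 5 and 19 adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.623 with an estimated correlation), and were not called without parental replicate 1 (0.15) or resistant replicate 2 (0.072).

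MAPK, YAP/TEAD and glycolysis lists were called downward in PC9, while the platinum transport list was not called. EREG, another EGFR ligand, fell by 4.44 ± 0.23 and EPHA4 by 2.71 ± 0.14, while the ERK phosphatase gene DUSP5 rose by 0.95 ± 0.13. MAPK feedback genes had 1 of 24 members higher and 10 lower, 3 and 11 adjusted over the list alone (camera adjusted p = 0.00996, adjusted p = 0.566 with an estimated correlation). DLC1 and NT5E fell by 6.17 ± 0.25 and 1.21 ± 0.10 among YAP/TEAD targets, which had 2 of 23 members higher and 9 lower, 4 and 9 adjusted over the list alone (camera adjusted p = 0.0308, adjusted p = 0.571 with an estimated correlation) and were not called without parental replicate 2 (0.132) or resistant replicate 1 (0.0862). The glycolytic genes GAPDH and TPI1 fell by 1.12 ± 0.08 and 1.00 ± 0.10. Hypoxia and glycolysis genes had 4 of 32 members higher and 13 lower, 5 and 14 adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.566 with an estimated correlation), and were not called without parental replicate 1 (0.0517) or resistant replicate 2 (0.0962). SLC31A1 rose by 0.79 ± 0.08, while the efflux pump gene ABCC4 and the channel gene LRRC8A fell by 0.91 ± 0.10 and 1.17 ± 0.11. GCLC, which limits glutathione synthesis, rose by 1.87 ± 0.10, but GPX2 and AKR1B10 fell by 2.61 ± 0.15 and 1.61 ± 0.12, and NRF2 targets were not called in PC9, with 6 of 33 members higher and 12 lower, 6 and 14 adjusted over the list alone (camera adjusted p = 0.112, adjusted p = 0.631 with an estimated correlation), though they were with voom weights (0.0161) and without resistant replicate 1 (0.00357).

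Histone, ribosomal protein and lncRNA lists were called in PC9, with no test of the cause. The histone genes H1-2 and H2BC11, whose transcripts mostly lack poly(A) tails and resemble each other in sequence, rose by 2.95 ± 0.11 and 2.34 ± 0.18. Replication-dependent histones had 10 of 25 members higher and 0 lower, 10 and 0 adjusted over the list alone (camera adjusted p = 0.000324, adjusted p = 0.547 with an estimated correlation), with a share of counts of 0.0118% and 0.0099% in parental and 0.0326% and 0.0287% in resistant libraries. Ribosomal protein genes had 0 of 58 members higher and 29 lower, 0 and 31 adjusted over the list alone (camera adjusted p = 2.26e-06, adjusted p = 0.571 with an estimated correlation), with 5.41% and 5.04% of counts in parental and 4.42% and 4.14% in resistant libraries. The imprinted RNA H19 fell by 7.23 ± 0.36 and MIR205HG by 1.198 ± 0.121 among lncRNAs studied in drug response, which had 2 of 58 members higher and 15 lower, 4 and 18 adjusted over the list alone (camera adjusted p = 0.00318, adjusted p = 0.547 with an estimated correlation).

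Libraries labelled H226 resistant differed from H226 parental libraries by the most genes, and the question of resistance cannot be separated there from that of origin. ALDH1A1, an aldehyde dehydrogenase gene, was higher by 306000-fold (95% counting interval 54900 to 12100000). The chemokine gene CXCL5 was at least 10100-fold higher, the EGFR ligand gene EREG 5300-fold, the microsomal glutathione transferase gene MGST1 4010-fold, KYNU 3570-fold, CNTN1 1440-fold and GPRIN3 1400-fold. MEG3 and MEG8, imprinted lncRNAs of chromosome 14, were at least 1180-fold and 579-fold higher, and LINC01322 at least 729-fold. The steroid dehydrogenase gene HSD3B1 was at least 5690-fold lower, KRT5 765-fold, MYO3A 638-fold, FAM110C 511-fold, GAS1 441-fold, the complement inhibitor gene SERPING1 427-fold and RAB17 362-fold. SLPI was lower by 12100-fold (95% counting interval 3360 to 100000). DISC1FP1, LINC02302 and DPP10-AS1 were at least 954-fold, 305-fold and 257-fold lower. The largest adjusted p among these genes was 2.97e-11. In all, 6790 genes were called higher (4988 protein-coding, 1306 lncRNA) and 6837 lower (4875 and 1390). Lists read as measures of RNA composition were not called. Mitochondrial messenger RNAs had 7 of 13 members higher and 0 lower (camera adjusted p = 0.12), and histones 2 of 25 higher and 14 lower (0.122). Ribosomal protein genes had 10 of 58 higher and 21 lower (0.295). Mitochondrial genes took 1.42% and 1.18% of counts in parental and 1.9% and 2% in resistant libraries.

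NRF2 targets were higher in the libraries labelled H226 resistant, while the list of platinum transport genes was not called. ME1 and UGDH, both NRF2 targets, were higher by 10.23 ± 0.23 and 4.07 ± 0.10, and GSTM3 lower at −3.39 ± 0.12. The NRF2 list had 29 of 33 members higher and 1 lower, 29 and 2 adjusted over the list alone (camera adjusted p = 3.46e-12, adjusted p = 0.193 with an estimated correlation). ABCC2, a pump that exports glutathione conjugates, was higher by 7.64 ± 0.13 and ABCG2 by 3.47 ± 0.14, while the copper exporter gene ATP7B was lower at −5.27 ± 0.17. ALDH3A1 and the progenitor factor gene SOX9 were higher by 12.11 ± 0.21 and 5.36 ± 0.16, and ALDH1A3 lower at −6.76 ± 0.32. Aldehyde dehydrogenases and stemness markers had 11 of 16 members higher and 2 lower, 11 and 2 adjusted over the list alone (camera adjusted p = 0.00374, adjusted p = 0.135 with an estimated correlation). BIRC3 and BAG1 were higher by 3.73 ± 0.11 and 1.28 ± 0.11 among anti-apoptotic genes, which had 10 of 12 members higher and 0 lower, 10 and 0 adjusted over the list alone (camera adjusted p = 0.00236, adjusted p = 0.135 with an estimated correlation).

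HLA class I and most interferon-stimulated genes were lower in the same libraries. NF-kB and cytokine genes were not called there and leaned the other way, with 14 of 26 members higher and 7 lower, 15 and 8 adjusted over the list alone (camera adjusted p = 0.122, adjusted p = 0.688 with an estimated correlation), and were called without parental replicate 2 (0.0425). HLA-C and B2M, which form the class I complex, were at −4.21 ± 0.12 and −2.52 ± 0.10, and the class I list had 0 of 18 members higher and 18 lower, 0 and 18 adjusted over the list alone (camera adjusted p = 8.47e-09, adjusted p = 0.173 with an estimated correlation). The viral restriction gene BST2 was at least 110-fold lower and MX1 at −5.24 ± 0.31, whereas OAS1 and HERC5 were higher by 4.35 ± 0.16 and 5.05 ± 0.20. Interferon-stimulated genes had 7 of 38 members higher and 27 lower, 7 and 27 adjusted over the list alone (camera adjusted p = 0.00188, adjusted p = 0.492 with an estimated correlation). The EGFR ligand gene AREG and the phosphatase gene DUSP4 were higher by 7.14 ± 0.29 and 3.37 ± 0.11, and EPHA4 at −2.26 ± 0.12, in a MAPK list that had 15 of 24 members higher and 4 lower, 16 and 4 adjusted over the list alone (camera adjusted p = 0.00133, adjusted p = 0.476 with an estimated correlation). NRG1, a ligand of ERBB3, was higher by 3.78 ± 0.11, while ERBB3 and GAS6 were at −7.04 ± 0.18 and −3.63 ± 0.16. Receptor tyrosine kinases and ligands had 6 of 29 members higher and 18 lower, 7 and 18 adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.398 with an estimated correlation). UPK3B and LRRN4, markers of mesothelium, were at −6.96 ± 0.18 and −6.45 ± 0.19, in a list of fibroblast and mesothelial markers that had 0 of 13 members higher and 9 lower, 0 and 9 adjusted over the list alone (camera adjusted p = 0.000294, adjusted p = 0.135 with an estimated correlation).

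Genes with known links to cisplatin or to these lines were followed whatever their values. The excision repair gene ERCC1 was at 2.35 ± 0.14, 0.35 ± 0.13 and −0.32 ± 0.14 in H226, H460 and PC9. It was not called in PC9 (adjusted p = 0.11, though called at −0.50 without resistant replicate 1 and at an adjusted p of 0.0475 with the replicate block), and its H460 call was lost without parental replicate 2 (0.18), resistant replicate 1 (0.36) or resistant replicate 2 (0.35). ERCC1 in H460 also lost its call with DESeq2 (adjusted p = 0.0819), DESeq2 size factors (0.0567), the stricter count filter (0.0522) and without H226 (0.0528). In H226, SLC31A1 and ATP7A were at −0.57 ± 0.08 and 2.66 ± 0.13. ATP7A had 0.25 ± 0.12 in PC9 (not called, adjusted p = 0.162). ATP7B was at 0.90 ± 0.20 in H460 and −0.89 ± 0.17 in PC9. The pump gene ABCC2 was at −0.36 ± 0.09 in H460, not called without resistant replicate 1 (−0.29), and at −0.31 ± 0.09 in PC9, not called without parental replicate 1 (−0.29) or resistant replicate 2 (−0.22), nor by edgeR on PC9 alone (adjusted p = 0.0598). EGFR was at −0.70 ± 0.10, −0.16 ± 0.10 and −0.54 ± 0.10, with H460 called only without parental replicate 1 (−0.34), and adjusted p = 0.268 with all libraries. KEAP1, the inhibitor of NRF2, was at 0.26 ± 0.09, −0.13 ± 0.09 and 0.11 ± 0.09, and was called in H226 alone (adjusted p = 0.0222), where leaving out any 1 of the 4 libraries ended the call (0.23 to 0.26). NFE2L2, which encodes NRF2, was at −0.89 ± 0.08, −0.76 ± 0.08 and 0.03 ± 0.08, the last not called (adjusted p = 0.918).

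Which genes changed the same way in all 3 lines was asked by intersecting the calls. NRP1, a co-receptor of VEGF and semaphorins, rose by 4.43 ± 0.11, 4.29 ± 0.12 and 0.47 ± 0.10 in H226, H460 and PC9. In the same order MGAT5B rose by 3.22 ± 0.20, 5.64 ± 0.24 and 1.25 ± 0.19, SFMBT2 by 7.35 ± 0.25, 2.77 ± 0.17 and 1.06 ± 0.18, and COL4A6 by 6.74 ± 0.16, 1.33 ± 0.11 and 0.65 ± 0.13. NF2 rose by 11.31 ± 0.24, 1.40 ± 0.12 and 0.71 ± 0.11, and KIAA1549L by 2.12 ± 0.19, 7.40 ± 0.38 and 0.53 ± 0.18. With 0 and 5 counts of NF2 in the H226 parental libraries, ± 0.24 understates the uncertainty of its H226 value. HERC5 rose by 1.499 ± 0.146 in PC9 beside its rises above. ARMCX3 was at least 433-fold higher in H226 and rose by 0.56 ± 0.12 and 2.37 ± 0.15 in H460 and PC9. GNG11 was at least 146-fold higher and rose by 1.03 ± 0.11 and 1.52 ± 0.13. PLAU, which encodes urokinase, was higher by 5850-fold (95% counting interval 1620 to 48300) in H226 and rose by 2.61 ± 0.14 and 0.38 ± 0.13 in the other lines. Among lncRNAs, LINP1, studied in repair of DNA ends, rose by 4.74 ± 0.34, 4.29 ± 0.33 and 0.88 ± 0.27, and SUCLG2-DT by 2.04 ± 0.18, 2.42 ± 0.19 and 0.95 ± 0.19. BVES-AS1, which overlaps BVES, was at least 55.4-fold higher in H226 and rose by 1.92 ± 0.41 in H460.

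Genes that fell in all 3 lines included GLUL, the glutamine synthetase gene, at −3.06 ± 0.13, −4.78 ± 0.16 and −0.85 ± 0.12. STXBP6 was at −4.78 ± 0.13, −3.52 ± 0.12 and −1.15 ± 0.12, and ARAP2 at −3.75 ± 0.14, −3.40 ± 0.17 and −0.38 ± 0.12. The actin-binding protein genes COBL and NEBL were at −5.42 ± 0.20, −1.26 ± 0.14 and −0.64 ± 0.14 and at −4.94 ± 0.14, −1.40 ± 0.12 and −0.62 ± 0.12. HR was at −2.17 ± 0.14, −0.58 ± 0.12 and −2.01 ± 0.14, and CRIP2 at −1.75 ± 0.20, −1.09 ± 0.21 and −1.79 ± 0.21. TRIQK was at −1.65 ± 0.12, −0.98 ± 0.12 and −1.93 ± 0.13, and ZNF655 at −0.51 ± 0.10, −0.36 ± 0.10 and −3.38 ± 0.12. DLEU2, a lncRNA host of microRNAs, was at −1.64 ± 0.15, −0.76 ± 0.15 and −0.69 ± 0.15, and SNHG8 at −0.35 ± 0.13, −2.18 ± 0.13 and −0.37 ± 0.13. LINC00938 was at −1.16 ± 0.17, −0.57 ± 0.17 and −0.66 ± 0.17. SLC16A4-AS1 was at −1.03 ± 0.15, −0.67 ± 0.15 and −0.55 ± 0.15, and NUTM2B-AS1 at −1.16 ± 0.13, −0.55 ± 0.13 and −0.44 ± 0.13. The largest adjusted p was 0.0498, of SNHG8 in PC9.

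Several of the shared calls were weak in 1 line and hung on single libraries. In PC9, PLAU was not called without parental replicate 1 (0.21) or resistant replicate 2 (0.23), KIAA1549L without parental replicate 1 (0.38), resistant replicate 1 (0.59) or resistant replicate 2 (0.45), and LINP1 without parental replicate 1 (0.72) or resistant replicate 1 (0.82). ARAP2 in PC9 was not called without parental replicate 2 (−0.34) or resistant replicate 1 (−0.29), nor was LINC00938 (−0.60 and −0.57) or SNHG8 (−0.21 and −0.18). NUTM2B-AS1 in PC9 was not called without parental replicate 1 (−0.48), parental replicate 2 (−0.42) or resistant replicate 1 (−0.27). In H460, ZNF655 was not called without parental replicate 2 (−0.28), resistant replicate 1 (−0.36) or resistant replicate 2 (−0.36), LINC00938 without parental replicate 2 (−0.54) or resistant replicate 2 (−0.35), and NUTM2B-AS1 without parental replicate 2 (−0.41). In H226, SNHG8 was not called without parental replicate 1 (−0.30) or resistant replicate 1 (−0.28). Other methods ended some of these calls too. SNHG8 in PC9 was not called by DESeq2 on the 12 libraries (adjusted p = 0.0814), with DESeq2 size factors (0.0641), the stricter filter (0.0598), without H226 (0.0592), or on PC9 alone by edgeR (0.128) and DESeq2 (0.153), nor SNHG8 in H226 with the stricter filter (0.0518). On PC9 alone, edgeR and DESeq2 did not call PLAU (0.109 and 0.13) or NUTM2B-AS1 (0.0546 and 0.0565), and without H226 KIAA1549L in PC9 was not called (0.0588).

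Shared calls were then counted against expectation, NF2 and GLUL among them. In all, 379 genes were called higher in every line (371 protein-coding, 6 lncRNA), against 122.8 expected of independent calls, and 289 lower (266 and 15), against 112.9. The higher count was 249 without PC9 parental replicate 2. Calls in opposite directions also exceeded their expectation, with 3226 genes between H226 and H460 (2391.7 expected), 1818 between H226 and PC9 (1343.8) and 1466 between H460 and PC9 (973.9). These opposite calls were 1.35, 1.35 and 1.51 times their expectation. In the same pairs, calls higher in both lines were 1.41, 1.55 and 1.83 times theirs, and calls lower in both 1.23, 1.39 and 1.79 times. Counts over 3 lines are not comparable with counts over pairs. The expectations above take all 28129 tested genes as able to be called in each line. As 3686 of them had 0 counts in every library of at least 1 line, these expectations are too low. The excess over 3 lines has no count of opposite calls beside it, so it does not by itself show a shared change. Without H226, 921 genes were called higher and 825 lower in both H460 and PC9, against 617.6 and 572.3 expected, and 1461 went opposite ways (1191.7 expected). The 3 comparisons share no control library.

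A change common to the lines was also tested in an additive model, in which disagreement between lines counts as spread. NR2F1-AS1 had a common change of −2.68 ± 0.25 (adjusted p = 0.00127) and NR2F1 fell as well (0.00628). TRIQK and CRIP2 had −1.52 ± 0.16 and −1.54 ± 0.19 (adjusted p = 0.00192 and 0.00334). HERC5 and SUCLG2-DT had 4.04 ± 0.65 and 1.81 ± 0.25 (adjusted p = 0.00994 and 0.00504), while the shared genes PLAU and NF2, driven by H226, did not pass (adjusted p = 0.223 and 0.295). In all, 974 genes rose (821 protein-coding, 117 lncRNA) and 867 fell (659 and 148). Left out 1 library at a time, these counts ranged from 298 to 949 and from 298 to 862, with moves of over 1.5 times for each of the 4 H226 libraries (298 to 365 higher, 298 to 337 lower) and each of the 4 H460 libraries (444 to 472 higher, 421 to 476 lower). With the replicate block 6 genes rose and 6 fell, although replicate numbers did not pair the libraries, while DESeq2 gave 2030 and 1915 and the mean of the line contrasts 5140 and 4610. The number of genes with a common change thus depends on the method. The 3 lines, not the 12 libraries, are the independent units of resistance. The SE and adjusted p of the additive model pool disagreement between lines with spread between libraries. They thus count libraries partly as replicates of resistance and can overstate certainty, for NR2F1-AS1 as well.

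For gene lists, the mean of the 3 line contrasts was tested, and the counts are of genes with a common change. NF-kB and cytokine genes had 4 of 26 members higher and 0 lower, 10 and 0 adjusted over the list alone (camera adjusted p = 2.13e-06, adjusted p = 0.124 with an estimated correlation). S phase genes, TK1 among them at 0.65 ± 0.17, had 7 of 35 members higher and 0 lower, 15 and 2 adjusted over the list alone (camera adjusted p = 6.9e-05, adjusted p = 0.159 with an estimated correlation). Heat shock and immediate early genes had 3 of 14 members higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 0.000156, adjusted p = 0.118 with an estimated correlation). Ribosomal protein genes had 0 of 58 members higher and 20 lower, 0 and 39 adjusted over the list alone (camera adjusted p = 3.25e-07, adjusted p = 0.56 with an estimated correlation). MAPK feedback genes had 1 of 24 members higher and 0 lower, 1 and 0 adjusted over the list alone (camera adjusted p = 0.000629, adjusted p = 0.458 with an estimated correlation), and were not called without H226 (0.419). Anti-apoptotic genes had 2 of 12 members higher and 0 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00178, adjusted p = 0.118 with an estimated correlation), and aldehyde dehydrogenases and stemness markers 3 of 16 members higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.000751, adjusted p = 0.118 with an estimated correlation). Without H226 neither was called (0.108 and 0.283). TGF-beta targets had 2 of 20 members higher and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.458 with an estimated correlation), and were not called without H226 resistant replicate 2 (0.0599). Fibroblast and mesothelial markers had 0 of 13 members higher and 1 lower, 0 and 3 adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.118 with an estimated correlation), and were not called without H226 (0.948). The NRF2 list was called upward in the mean though no member passed alone, with 0 of 33 members higher and 0 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 6.9e-05, adjusted p = 0.458 with an estimated correlation), and downward without H226 (3.6e-06). The HLA class I list was called downward in the mean, again with no member passing and with H460 and PC9 called upward, with 0 of 18 members higher and 0 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.0412, adjusted p = 0.609 with an estimated correlation). That call was reversed without H226 (1.69e-05) and lost without H226 parental replicate 2 (0.0556), H226 resistant replicate 1 (0.0617), H460 parental replicate 1 (0.0564), PC9 parental replicate 2 (0.0531) or PC9 resistant replicate 2 (0.0708).

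How far the lines differed was tested directly. ABCG2 rose by 3.47 ± 0.14 in H226 and fell by 2.26 ± 0.12 in H460 (adjusted p of the difference between lines = 2.23e-17). OAS1 rose by 4.35 ± 0.16 and fell by 2.94 ± 0.13 in the same lines (1.15e-18), and HLA-C fell by 4.21 ± 0.12 and rose by 1.44 ± 0.11 (2.66e-19). SLC31A1 fell by 1.32 ± 0.08 in H460 and rose by 0.79 ± 0.08 in PC9 (3.73e-13). AKR1B10 fell by 5.24 ± 0.14 and 1.61 ± 0.12 in H460 and PC9, and differed between lines (8.4e-21). NRF2 targets differed between H226 and H460 as a list (camera adjusted p = 2.59e-14, adjusted p = 0.177 with an estimated correlation), as did interferon-stimulated genes (6.62e-08, and 0.198 estimated) and HLA class I genes (1.96e-09, and 0.177 estimated). In all, 14056 genes differed between lines, with 11333 between H226 and H460, 9814 between H226 and PC9 and 7780 between H460 and PC9. Without H226, 7551 genes differed between H460 and PC9. Of the tested genes, 3686 had 0 counts in every library of at least 1 line, and the 1044 genes with counts in a single line cannot pass this test. Fold changes of H226 and H460 correlated across 16227 genes at r = −0.012, those of H226 and PC9 at −0.044 and those of H460 and PC9 at −0.018 (Spearman −0.02, 0.017 and 0.05), and genes are not independent replicates.

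**Figure D3:**
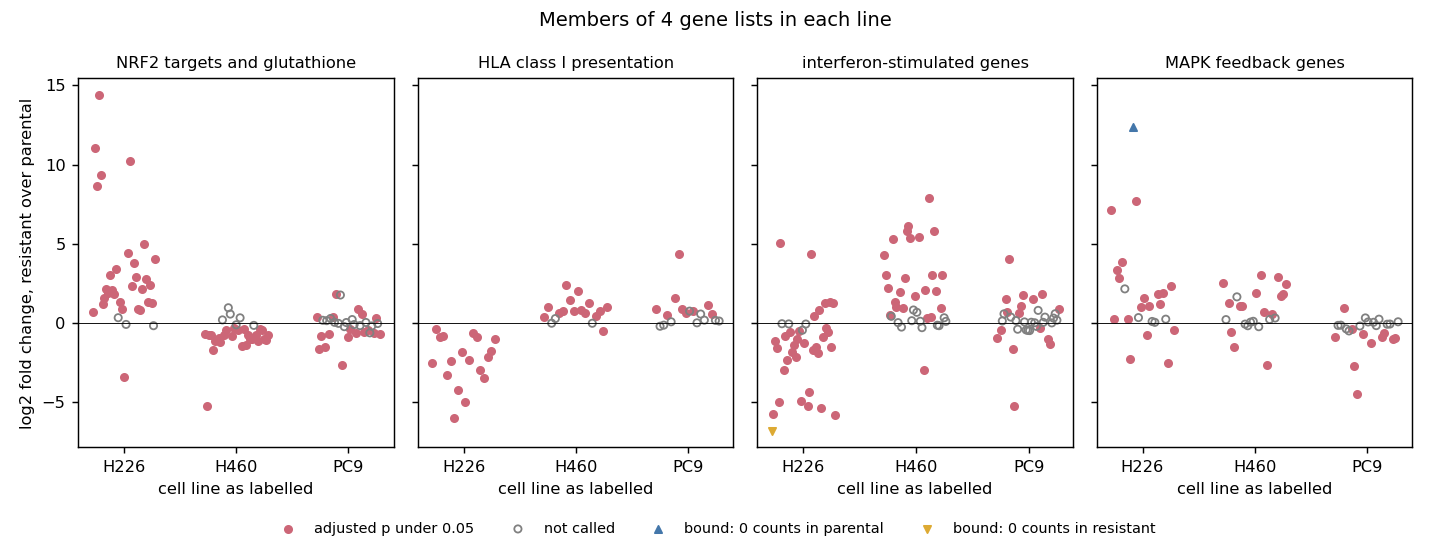
Log2 fold change of resistant over parental for each tested member of 4 gene lists, by line, with filled points for an adjusted p under 0.05, open points for other genes and triangles for bounds against 0 counts. NRF2 targets lie mostly above 0 in H226 (29 of 33 called higher) and below 0 in H460 (27 called lower), and HLA class I genes show the opposite.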

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

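Named genes and lists were put forward here when the test of a difference between lines passed and at least 2 lines called them in opposite directions. That rule was fixed in advance, while the 3 tests of where the libraries labelled H226 resistant come from were chosen only after the result was seen. Numbers in parentheses are adjusted p of the difference between lines. The rule took 72 genes and 9 pairs of lines for a list.

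The pump genes ABCC2 and ABCG2 were among 9 genes that rose in H226 and fell in both H460 and PC9, namely MGST1 (1.03e-22), KYNU (9.55e-23), UGDH (5.39e-20), ALDH3A1 (3.2e-23), ABCC2 (2.45e-22), ABCG2 (2.23e-17), SEMA3E (7.57e-16), AKR1B10 (8.4e-21) and TRIB3 (1.46e-15). Rising in H226 and falling in H460 were CXCL5 (1.53e-21), ME1 (1.28e-20), OAS1 (1.15e-18), LGSN (1.19e-14), DUSP6 (3.81e-14) and MT-ND3 (2.39e-07), and rising in H226 and falling in PC9 were EREG (4.36e-16), LINC01322 (1.63e-10), HPGD (1.02e-18), TSPYL5 (5.74e-16) and GAPDH (2.13e-11). HLA-B, HLA-C and B2M were among those that fell in H226 and rose in both other lines, which were GAS1 (1.78e-15), HLA-C (2.66e-19), B2M (1.67e-16), OASL (8.77e-17), HLA-B (1.09e-15), CRIM1 (1.18e-15), JUN (9.63e-13) and H2BC11 (1.86e-10). Falling in H226 and rising in H460 were ERBB3 (4.7e-18), GAS6 (5.38e-14), DRD2 (1.04e-10), SPRY4 (1.31e-13) and PDIA4 (4.19e-10), and falling in H226 and rising in PC9 were SERPING1 (6.59e-14), MX1 (5.96e-12), NMU (3.82e-11), RRAGD (1.9e-12) and H1-2 (1.54e-15).

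AREG, TNC and PMEPA1 were among the 16 that rose in H226 and H460 and fell in PC9, namely ALDH1A1 (4.07e-11), AREG (3.65e-14), NRG1 (4.74e-16), SOX9 (5.51e-17), TNC (3.85e-16), LINC00973 (5.61e-06), PMEPA1 (1.7e-19), CXCL1 (4.13e-12), ENO2 (4.13e-16), KLF12 (2.76e-15), HMGA2 (1.56e-18), LINC01060 (4.41e-11), GINS1 (1.03e-08), CDC20 (7.95e-10), TPI1 (1.64e-10) and LRRC8A (3e-11). The copper exporter gene ATP7B was in the group that rose in H460 and fell in H226 and PC9, with FAM110C (5.93e-16), BST2 (4.57e-13), EPHA4 (3.73e-15), ATP7B (6.05e-16) and CDYL2 (2.8e-15). SLC31A1, the copper importer gene, rose in PC9 and fell in H226 and H460, as did the others of SLPI (1.84e-20), SLC31A1 (3.73e-13), REEP1 (1.33e-12) and NDC80 (6.13e-10). Genes that rose in H226 and PC9 and fell in H460 were PSAT1 (6.12e-17), DUSP5 (3.24e-13) and GCLC (1.16e-14). Between H460 and PC9 alone, OLFML3 (3.21e-12), NT5E (2.41e-16), SLITRK6 (3.7e-14) and DLGAP5 (1.19e-08) rose in H460 and fell in PC9, and MUCL3 (2.32e-07) and RBBP8 (9.44e-12) did the reverse.

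Lists were compared between pairs of lines with camera, and none of these differences held with an estimated correlation. The change of NRF2 targets was higher in H226 than in H460 (2.59e-14, and 0.177 with an estimated correlation). Changes of interferon-stimulated genes (6.62e-08, 0.198 estimated), HLA class I genes (1.96e-09, 0.177 estimated) and receptor tyrosine kinases (1.81e-06, 0.177 estimated) were lower in H226 than in H460, and those of HLA class I genes also than in PC9 (1.09e-09, 0.144 estimated). Changes of MAPK feedback genes were lower in PC9 than in H226 (2.99e-05, 0.233 estimated) and H460 (5.29e-05, 0.332 estimated). Those of YAP/TEAD targets (0.000438, 0.348 estimated) and hypoxia genes (7.59e-05, 0.332 estimated) were lower in PC9 than in H460.

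The libraries labelled H226 resistant were as close to another line as to H226 parental cells, and many of the opposite calls above involve H226. A difference in RNA selection between the 2 H226 groups is argued against, since histone genes took 0.659% and 0.671% of counts in H226 parental libraries and 0.5% and 0.521% in those labelled resistant (1.3-fold), against at most 0.0326% in H460 and PC9. Other cells mixed into cells like H226 parental ones are argued against as well, since the 14 genes abundant in H226 parental cells and absent from H460 and PC9 stood at a median of 0.609% of their parental level. Cells of another origin or a wrong label remain a candidate explanation, since 41 protein-coding genes, BAP1 and NF2 among them, were under 0.2 CPM in H226 parental libraries and at 5 CPM or more in all 5 other groups, against 5 such genes for H460 and 0 for PC9. The rule for these 41 genes required them to be higher in the libraries labelled resistant, so that rise is no test of other explanations. The 14 genes above were chosen without those libraries and were lower there as a median, while the histone share differed 1.3-fold. Other steps of library preparation were not tested. A large biological change during resistance stays open. PHF7, beside BAP1 on chromosome 3, had 0 counts in both H226 parental libraries and 144 and 143 in those labelled resistant. No genotype was available to tell whether such genes are deleted in H226 parental cells.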

How the results depend on the processing

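Leaving H226 out of results other than the common change, and the single-dispersion form of the quasi-likelihood test, were alternatives chosen only after the result was seen, and the others were planned. Of 256 gene results in the 3 lines, 199 kept their direction and their side of the threshold under every alternative and none reversed. With the log2 fold change of at least 1, 50 of them were no longer called, by its construction. DESeq2 on the 12 libraries lost 6, DESeq2 size factors 2, no count filter 0, the stricter filter 3, edgeR and DESeq2 on each line alone 4 and 3, and a fit without H226 lost 3.

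Counts of calls moved by over 1.5 times as follows. A minimum fold can only remove calls, and calls of at least 1 in log2 fold change were 4437 higher and 4303 lower in H226, 2937 and 1936 in H460, 924 and 1099 in PC9, 69 and 32 shared by the lines, and 503 and 379 for the common change. For the common change, which was 974 and 867, DESeq2 gave 2030 and 1915, a single dispersion 1897 and 1870, and the mean of the 3 line contrasts, which does not count disagreement between lines as spread, 5140 and 4610. Without H460 the common change had 1316 genes lower, and without PC9 it had 1914 higher and 1749 lower. The cause was not tested for the DESeq2, single-dispersion and left-out-line counts. Without H226, 921 genes were higher and 825 lower in both remaining lines and 7551 differed between them, since fewer lines have to share a call and only 1 pair is compared. No scaling moved the median of all genes by over 0.1.

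The replicate number did not pair the libraries, as deviations of same-numbered libraries correlated at 0.019, −0.011 and 0.076 in H226, H460 and PC9. With the replicate block, which leaves 3 residual degrees of freedom in the fit of the lines, the common change had 6 genes higher and 6 lower, the HLA class I list lost its call in the mean of the lines, and the cholesterol list gained one in PC9 (0.0472). ERCC1 in PC9 gained a call, and other gene calls of the text were the same.

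Left out 1 library at a time, with the lone library of a group assumed to vary like the others, calls in H226 ranged from 5365 to 5788 higher and from 5619 to 5890 lower. In H460 they ranged from 4135 to 4303 and from 3606 to 4126, and in PC9 from 1816 to 2396 and from 2150 to 2527. Shared genes ranged from 249 to 378 higher and from 221 to 338 lower, the common change from 298 to 949 and from 298 to 862, and the genes that differed from 12821 to 14169. Only the common change, PC9 higher and shared higher moved by over 1.5 times, the latter both without PC9 parental replicate 2. Lists called ranged from 8 to 9 in H226, 14 to 17 in H460, 7 to 11 in PC9 and 10 to 11 in the mean. Not named elsewhere, mitochondrial messenger RNAs in H226 without parental replicate 1 (0.0302) and stress response genes in PC9 without parental replicate 2 (0.0334) gained calls.

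List calls rested on the preset correlation. With an estimated correlation, camera called 0 of 37 lists in H226, H460, PC9 and the mean, against 8, 15, 10 and 11 (unadjusted p under 0.05 for 5, 7, 1 and 6), and with voom weights and the preset correlation 10, 16, 13 and 12. Gained with voom were YAP/TEAD targets (0.0441) and histones (0.00761) in H226, cancer-testis antigens in H460 (0.043), NRF2 targets (0.0161), translesion and mismatch repair (0.019) and cholesterol genes (0.019) in PC9 and lncRNAs in the mean (0.0172). Without H226, 2 list results in the mean reversed, as H226 alone carried their direction: NRF2 targets were lower (3.6e-06) and HLA class I genes higher (1.69e-05). Another 4 lists of the mean lost their call without H226, and interferon-stimulated genes (3.6e-06), receptor tyrosine kinases (0.0101), mesenchymal markers (0.011) and histones (0.042) gained one upward and lncRNAs (0.000368), stress response genes (0.0411) and mitochondrial messenger RNAs (0.042) downward. Chromosome windows of 5 Mb gave 30.8%, 11.7% and 22.5% called in H226, H460 and PC9, against 37.4%, 17.4% and 33.4% for windows of 10 Mb, while chromosome arms gave 72.7%, 34.1% and 45.5%, and the cause was not tested. Depth limited folds of genes at 0 counts to bounds of 3 counts per library.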

Other observations

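Among the tests here, the reading of chromosome windows on genes of at least 1 CPM was chosen only after the result was seen. The other splits of the libraries and the windows themselves were planned.

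Lists of platinum transport, metallothionein, nucleotide excision repair, translesion and mismatch repair, p53, pro-apoptotic and cholesterol genes had no call in any line with all libraries and camera on log2 CPM. Platinum transport and copper genes had 13 of 25 higher and 6 lower in H226, 6 and 9 in H460 and 1 and 8 in PC9 (13 and 6, 7 and 10, and 3 and 8 adjusted over the list alone), with a camera adjusted p of at least 0.122, and adjusted p = 0.345 or more with an estimated correlation. Metallothioneins had 3 of 5 higher and 2 lower in H226, 3 and 0 in H460 and 0 and 2 in PC9 (3 and 2, 3 and 0, and 0 and 2 adjusted over the list alone), with a camera adjusted p of at least 0.0502, and adjusted p = 0.436 or more with an estimated correlation. Nucleotide excision repair genes had 9 of 33 higher and 8 lower in H226, 13 and 9 in H460 and 11 and 2 in PC9 (10 and 8, 13 and 9, and 11 and 3 adjusted over the list alone), with a camera adjusted p of at least 0.139, and adjusted p = 0.566 or more with an estimated correlation. Translesion synthesis and mismatch repair genes had 8 of 19 higher and 7 lower in H226, 5 and 4 in H460 and 8 and 2 in PC9 (8 and 7, 5 and 5, and 10 and 2 adjusted over the list alone), with a camera adjusted p of at least 0.0502, and adjusted p = 0.571 or more with an estimated correlation. They were called in PC9 with voom weights (0.019) and without resistant replicate 1 (0.0239). Targets of p53 had 12 of 34 higher and 9 lower in H226, 14 and 7 in H460 and 6 and 4 in PC9 (13 and 9, 15 and 7, and 6 and 4 adjusted over the list alone), with a camera adjusted p of at least 0.242, and adjusted p = 0.714 or more with an estimated correlation. In H460 they were called without parental replicate 1 (0.0387). Pro-apoptotic genes had 11 of 23 higher and 6 lower in H226, 9 and 5 in H460 and 3 and 1 in PC9 (11 and 7, 9 and 5, and 3 and 1 adjusted over the list alone), with a camera adjusted p of at least 0.557, and adjusted p = 0.741 or more with an estimated correlation. Cholesterol synthesis genes had 3 of 24 higher and 11 lower in H226, 4 and 11 in H460 and 4 and 2 in PC9 (3 and 11, 4 and 11, and 5 and 2 adjusted over the list alone), with a camera adjusted p of at least 0.0682, and adjusted p = 0.571 or more with an estimated correlation. In PC9 they were called with voom weights (0.019), with the replicate block (0.0472) and without resistant replicate 2 (0.0211).

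Epithelial, mesenchymal, squamous, alveolar, neuroendocrine, cancer-testis and HLA class II lists had no call in any line either in that test. Epithelial markers had 8 of 30 higher and 13 lower in H226, 5 and 8 in H460 and 6 and 2 in PC9 (9 and 13, 7 and 10, and 6 and 2 adjusted over the list alone), with a camera adjusted p of at least 0.174, and adjusted p = 0.492 or more with an estimated correlation. Mesenchymal markers had 10 of 30 higher and 13 lower in H226, 14 and 6 in H460 and 7 and 3 in PC9 (10 and 13, 14 and 8, and 9 and 5 adjusted over the list alone), with a camera adjusted p of at least 0.0887, and adjusted p = 0.436 or more with an estimated correlation. Without H226 they were called upward in the mean of the lines (0.011). Squamous and basal markers had 4 of 19 higher and 8 lower in H226, 4 and 3 in H460 and 3 and 5 in PC9 (4 and 9, 4 and 3, and 4 and 6 adjusted over the list alone), with a camera adjusted p of at least 0.12, and adjusted p = 0.345 or more with an estimated correlation. Alveolar and airway markers had 8 of 18 higher and 4 lower in H226, 5 and 2 in H460 and 2 and 4 in PC9 (8 and 4, 5 and 2, and 2 and 4 adjusted over the list alone), with a camera adjusted p of at least 0.233, and adjusted p = 0.444 or more with an estimated correlation. Neuroendocrine markers had 4 of 12 higher and 1 lower in H226, 4 and 2 in H460 and 1 and 2 in PC9 (4 and 2, 4 and 2, and 1 and 2 adjusted over the list alone), with a camera adjusted p of at least 0.449, and adjusted p = 0.641 or more with an estimated correlation. Cancer-testis antigens had 2 of 9 higher and 1 lower in H226, 4 and 0 in H460 and 2 and 1 in PC9 (2 and 1, 4 and 0, and 2 and 1 adjusted over the list alone), with a camera adjusted p of at least 0.0972, and adjusted p = 0.326 or more with an estimated correlation. In H460 they were called with voom weights (0.043). HLA class II genes had 0 of 6 higher and 3 lower in H226, 0 and 1 in H460 and 2 and 0 in PC9 (0 and 3, 0 and 0, and 2 and 0 adjusted over the list alone), with a camera adjusted p of at least 0.155, and adjusted p = 0.547 or more with an estimated correlation. In PC9 they were called without parental replicate 2 (0.0389).

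Immune and endothelial marker lists had no call in any line in the same test, while fibroblast and mesothelial markers were called in H226. Immune cell markers had 1 of 9 higher and 2 lower in H226, 3 and 1 in H460 and 1 and 0 in PC9 (1 and 1, 3 and 1, and 1 and 0 adjusted over the list alone), with a camera adjusted p of at least 0.466, and adjusted p = 0.641 or more with an estimated correlation. Endothelial markers had 2 of 10 higher and 4 lower in H226, 3 and 0 in H460 and 0 and 1 in PC9 (2 and 5, 3 and 0, and 0 and 1 adjusted over the list alone), with a camera adjusted p of at least 0.091, and adjusted p = 0.284 or more with an estimated correlation. In H460 they were called without parental replicate 1 (0.0426) or resistant replicate 1 (0.0323). Red cell markers had 1 of 2 higher and 0 lower in H226, 0 and 0 in H460 and 0 and 0 in PC9 (1 and 0, 0 and 0, and 0 and 0 adjusted over the list alone), too few for camera. No reading on contamination is taken from single members.

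The count of genes with a common change, NR2F1-AS1 among them, was set against other splits of the libraries into the same numbers within each line. Of 100 splits drawn from 108 possible, 1 gave as many as 1841 genes, the real one. The highest of the others gave 1641, in a split that kept the groups of all 3 lines whole and exchanged parental and resistant in 2 of them. Splits that kept the groups whole, 3 besides the real one, gave 1172 or more, and splits that broke up at least 1 group gave at most 111. Splits that broke up a group counted the difference between parental and resistant libraries of that line as spread, so few calls could result. They therefore cannot tell an accident of grouping from a change common to the lines. Among splits that kept the groups whole the real one was only somewhat higher, so the count does not show that the lines changed alike.

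Neighbouring genes moved together along several chromosomes of the resistant lines. In H460, genes on chromosome 6 from 60 to 70 Mb had a median log2 fold change of −1.516 over 21 genes and those on chromosome 12 from 80 to 90 Mb one of −1.198 over 38 genes. In PC9, chromosome 18 from 50 to 60 Mb had −1.074 over 63 genes, from 60 to 70 Mb −1.049 over 39 genes and from 70 to 80 Mb −0.834 over 56 genes, while from 20 to 30 Mb it had 0.812 over 54 genes. Of 305 windows of 10 Mb with at least 10 genes, 53 in H460 (17.4%), 102 in PC9 (33.4%) and 114 in H226 (37.4%) differed from random sets of genes, where 2e-04 was the smallest p that 10000 sets can give. The windows say nothing of the single genes in them.

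A change of chromosome dosage is a candidate explanation of these windows and was tested through the share of genes that followed the window. In called windows of the 3 lines a median of 67.9% of the tested genes moved with the window. That lay between the 75% predicted with dosage and the 60% predicted without it, so the test left dosage open. Among genes of at least 1 CPM in the line, the median was 81.4% in PC9, above the upper bound, and 71.4% in H460, between the bounds (other windows 58% and 59.1%). Windows were called by a shifted median, and genes were then counted on the side of that median. A raised share is thus partly built in, and passing the bound in PC9 does not favour dosage. Shares under 60% did occur in longer segments, with medians of 54.3% in H460 and 57.9% in PC9 over the tested genes of called chromosome arms. Dosage stays open in both lines. H226 had 75.9% but its origin is in doubt. Shared regulation of neighbouring genes could give such windows too, and no DNA measurement was available to tell them apart.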
